A study of Mus musculus with 2 samples.

How the data were processed

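The series holds 2 single-cell RNA libraries of CD45-positive lung cells, PBS and DT, each made from 1 sort with 4 mice per group in the study's design, and no label ties a cell to an animal. The submitters' processing notes name Partek, Seurat, STAR and the mm10 genome, while aligner settings, the annotation release and tool versions are not given in the sources used here. The deposited tables hold log2(CPM + 1) per cell and gene, for 16184 genes, 5702 PBS cells and 6203 DT cells. The plan had been written for counts, so the log was undone and each cell was divided by its smallest step, which gave whole numbers: 100% of the values above 0 were whole within 1%, among them 100% of the values of up to 5 UMIs (9713332 in PBS, 9335964 in DT). These recovered UMIs were used throughout, and means of the deposited log2 values served as an alternative. In all, 8 barcodes occurred in both libraries.

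The filters, the clustering, the marker and gene lists, the rule for named genes and the settings to compare were fixed before the data were examined. Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which removed 51 PBS cells and 307 DT cells, and no cell exceeded 8.0% mitochondrial UMIs. Scrublet, run per library at an expected doublet rate of 6%, marked 2 of 5651 PBS cells and 0 of 5896 DT cells, under the set limit of 0.5%, so no cell was removed as a doublet. Both libraries were clustered together without integration: counts were scaled to 10000 per cell and logged, 2000 variable genes were taken without immunoglobulin and T cell receptor segments, mitochondrial, ribosomal and haemoglobin genes, and 30 principal components, 15 neighbours and Leiden resolution 1 gave 34 clusters. A cluster took the name of a marker list when at least 3 of its markers were up by at least 1 on the log2 scale and seen in at least 10% of its cells, unless its 10 leading genes held more markers of another class. Cluster 5, called CD8 T cell by this rule, leads with gamma-delta receptor genes (Trdc, Tcrg-C2) and is named in the text by its class alone. Clusters 23, 28 and 29 had the highest doublet scores.

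UMIs were summed over the cells of a class for the 6 classes with at least 200 cells in both libraries and scaled to CPM of that sum. Ratios were formed with 5 CPM added to both sides. Intervals are exact 95% intervals, Clopper-Pearson for shares of cells and conditional binomial (exact Poisson) for ratios of UMIs, and cover counting error only. A count of 0 was bounded by a floor of 3 counts over the class. A list's median log2 ratio was taken over members with at least 20 UMIs in the class, and its percentile came from 10000 random lists of the same size matched in 20 bins of expression, or 2000 for alternatives. In all, 32 lists were fixed, covering T, NK, B, neutrophil and macrophage states, interferon, antigen presentation, cell cycle, p53, metabolism, dissociation, cell death and free RNA of other cell types, and the result of each is given at least once. Genes named for a class were the 10 highest and 10 lowest of the 4 largest classes, and the 3 highest and lowest of the others, among those with at least 100 UMIs in both libraries together, at least 50 CPM in one of them, a ratio of at least 1.5 and an interval without 1. Further named genes were members of the lists discussed and 12 genes fixed in advance, such as Scgb1a1, Pdcd1 and Arg1. Cycling cells were those with at least 2 of 6 mitotic genes after thinning to 1000 UMIs.

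No test between the groups was run, since 1 library per group gives no measure of the spread between mice. Sex was called per cell from Xist and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty). The settings varied by plan were the cell filters, the mitochondrial limit, the Leiden resolution (0.5 and 2), the centring of principal components per library, the denominator of the shares, the naming of single cells, the scaling (trimmed mean and median-of-ratios factors, computed in Python), the weight of each cell, the depth per cell, the added CPM (1 and 20), the member minimum (100 UMIs) and free RNA (a mean profile at 10% of UMIs subtracted). Settings chosen after seeing the data left out the 6% of cells with the highest doublet scores, or used male-called or female-called cells alone. Others gave clusters the same weight in both libraries, or used means of the deposited log2 values. Expression within called cells was computed only for classes with at least 100 such cells in both libraries, while shares within called cells had no such minimum. Neutrophil-specific list members were those with at least 10 times the CPM in the neutrophil class that they had in the T cell class, and were parted by taking every other one in alphabetical order.

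The steps were tested on simulated data with known changes, drawn as Poisson counts of the class sums around a pooled profile of each class. These data hold no variation between cells, droplets or mice. The rates below therefore cover counting error only and say nothing about genes carried by a few droplets. The rule for named genes, without the limit of 10 each way, picked 35.3% to 46.7% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold in the 4 largest classes, and 0% of unchanged genes in 3 classes and 0.0418% in neutrophils. Of 100 unchanged lists, 2% to 8% fell outside the 95% range, and all 20 lists moved 1.5-fold rose above it. Apart from these simulations, the UMIs of 50 kept cells were turned into log2 values and back, which returned 100% of 94315 values. The smallest count of each cell was supplied, so this checks rounding only and not how the step was found. Coordinates came from GENCODE M21 (GRCm38). The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, with random seed 7.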

Results

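Leukocytes were profiled by single-cell RNA sequencing of 10x Genomics 3′ libraries from lungs that carried tumours of HKP1, a mouse lung cancer line given through the tail vein. The mice carried an Scgb1a1-driven, tamoxifen-inducible Cre and iDTR, a diphtheria toxin receptor that Cre switches on, so that toxin kills cells of the Scgb1a1 lineage. Scgb1a1 marks club cells, the secretory cells of the small airways. One group received PBS as the control and the other received diphtheria toxin (DT). Per the treatment protocol, both groups received tamoxifen at 2 mg per 20 g on 5 days, from day 3 to day 7. Anti-PD-1 antibody was given at 250 µg per mouse at day 6. The toxin was given as 2 doses of 600 ng per 20 g at days 8 and 9. The lungs were irradiated with 4 Gy on each of 3 days from day 10 to day 12. The design text names the radiation for both groups but not the antibody, which comes from that protocol alone. Viable (DAPI-negative), CD45-positive cells were collected 24 to 48 h after radiation. The study's design names 4 mice per group, and each group is 1 library, so there are no replicates. The title and the design set the question: how the immune cells of irradiated, tumour-bearing lungs differ when club cells have been removed.

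The PBS library held 5702 cells with 31089434 unique molecular identifiers (UMIs) in all, at a median of 3719 UMIs and 1583 genes per cell. The DT library was shallower per cell, with 6203 cells, 27896059 UMIs, and medians of 2909 UMIs and 1350 genes. After filtering, 5651 PBS cells and 5896 DT cells were kept and fell into 34 clusters. Clusters were named from marker genes and merged into classes, so a class name here means cells like that type. With 1 library per group no test between groups was possible. Each value below is a description of these libraries, and every interval is a 95% interval for counting error alone, which says nothing about differences between mice. Log2 ratios are DT over PBS of UMI counts summed over a class and scaled to a common total (CPM), after 5 CPM were added to both sides, while plain ratios and all intervals are without that addition.

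Scgb1a1 RNA was far lower in DT than in PBS in each of the 6 immune classes compared. Scgb1a1 (chromosome 19, 9083636 to 9087958, GRCm38), which encodes the secretoglobin that club cells release, stood at 37.1 CPM over all non-epithelial cells of PBS (1145 UMIs) and at 0.908 CPM in DT (25 UMIs), which is 40.8 times as much in PBS (27.5 to 63.3). In the T cell class it was 39.5 CPM against 0.318 CPM, from 265 and 2 UMIs, with a PBS to DT ratio of 124 (34.0 to 1029). The ratio was smaller in mononuclear phagocytes, at 13.3 (8.11 to 23.1), from 241 and 17 UMIs. Over all non-epithelial cells Scgb3a2, another secretoglobin of club cells, gave 207 UMIs in PBS and 0 in DT, so it was at least 61.5-fold lower in DT against a floor of 3 counts, and Cyp2f2, a cytochrome P450 of club cells, gave 39 and 0 UMIs, at least 11.6-fold lower. Sftpc, the surfactant protein of alveolar type 2 cells, was nearer to even, at 8.97 CPM in PBS and 7.30 CPM in DT (ratio 1.23, 1.02 to 1.48). Its PBS to DT ratios were 0.997 in mononuclear phagocytes, 1.94 in T cells and 1.83 in neutrophils. Sftpa1, another surfactant gene of those cells, had a ratio of 2.27 (1.46 to 3.62).

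The sort for CD45 is meant to leave club cells out, so these transcripts are not a measure of depletion in the tissue. Scgb1a1 was seen in 16.8% of PBS T cells (median depth 4252.5 UMIs), 13.4% of PBS B cells (2816 UMIs) and 14.2% of PBS neutrophils (2169.5 UMIs), none of which should express it, and in 0.154%, 0.181% and 0.152% of the same DT classes at 4007, 2438.5 and 2001.5 UMIs. The epithelial class, by contrast, had Scgb1a1 UMIs in 9 of 21 PBS cells and 4 of 80 DT cells, at 1131 and 1041 CPM, but Scgb3a2 gave 29 and 0 UMIs there and Cyp2f2 57 and 0. As lists, club cell RNA had a median log2 ratio of -0.54 over 4 measured members in the T cell class (2 higher and 2 lower, Scgb1a1 and Scgb3a2) and alveolar type 2 RNA had -0.45 (4 of 4 lower), each below its range for random lists. Endothelial and stromal RNA, at 0.18 (6 of 6 higher), lay within it.

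**Figure D1:**
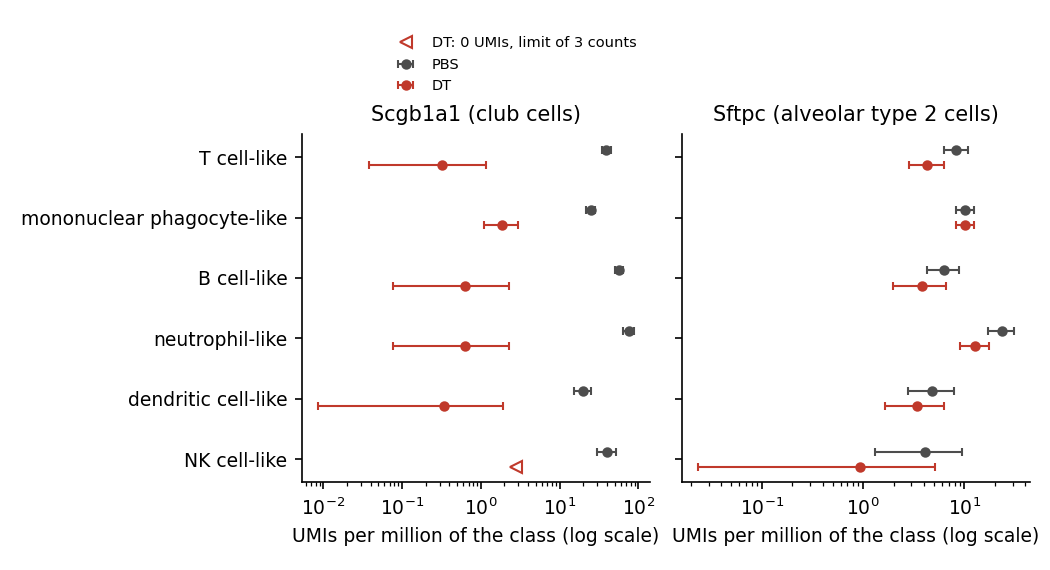
UMIs of Scgb1a1 and Sftpc in 6 classes of the PBS (grey) and DT (red) libraries, scaled to CPM of the class on a log axis, with lines for the 95% counting interval and an open triangle for the limit of 3 counts where DT had 0 UMIs. Scgb1a1 lies lower in DT in each class shown, at 39.5 and 0.318 CPM in T cells, while Sftpc lies much closer between the libraries.

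Neutrophils made up a larger share of the sorted cells in DT, and B cells a smaller one. The neutrophil class held 14.2% of PBS cells (13.3 to 15.1) and 22.3% of DT cells (21.2 to 23.4), a ratio of 1.57. B cells held 25.1% (24.0 to 26.3) and 18.7% (17.7 to 19.7), a ratio of 0.745. T cells held 23.04% and 22.03% (ratio 0.956), mononuclear phagocytes 20.4% and 20.0% (0.982), natural killer (NK) cells 5.45% and 4.78% (0.878) and dendritic cells 5.13% and 4.94% (0.962), each ratio with a counting interval that included 1. Of the stromal cells that passed the sort, endothelial cells held 1.66% and 1.34% and fibroblasts or other stroma 0.460% and 0.560%. Proliferating cells held 1.96% and 1.56%, basophils or mast cells were 6 and 7 cells, and 2.16% and 2.32% of cells had no name.

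Among mononuclear phagocytes, the cells that patrol vessels and airspaces were fewer in DT. Nonclassical monocytes, the Ace- and Treml4-positive patrolling cells, went from 4.53% of all cells in PBS (256 cells) to 1.78% in DT (105 cells), a ratio of 0.393. Alveolar macrophages, led by Chil3, Ctsk and Marco, went from 2.14% (121 cells) to 0.831% (49 cells), a ratio of 0.388. Interstitial or tumour macrophages, which carry C1q genes, Apoe and Trem2, held 4.23% and 5.80%, a ratio of 1.37. Their clusters differed: cluster 15, led by Gpnmb, had a ratio of 1.63, cluster 21, with a median doublet score of 0.157, 1.47, and cluster 22, led by Pf4, 0.983. Cluster 3, the largest of the class and named by class alone, which shares leading genes such as Ccl24 and Cxcl9 with cluster 21, held 6.53% and 8.41% (ratio 1.29), and classical monocytes held 2.92% and 3.15%. Plasmacytoid dendritic cells, the main makers of type I interferon, held 1.49% and 0.882%, a ratio of 0.593. Regulatory T cells, at 3.96% and 4.31%, differed by less than their counting intervals.

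Depth can set some of these shares: the filter on UMIs and genes removed 51 PBS cells and 307 DT cells, and the main nonclassical monocyte cluster had a median of 5180 UMIs in PBS and 1392 in DT. Epithelial cells, at 0.372% (21 cells, median 8627 UMIs) and 1.36% (80 cells, median 992.5 UMIs), had a ratio of 3.65, which came to 0.990 when each cell was named alone by its highest marker score, and the nonclassical ratio was 0.236 with at least 500 genes and 1000 UMIs per cell.

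**Figure D2:**
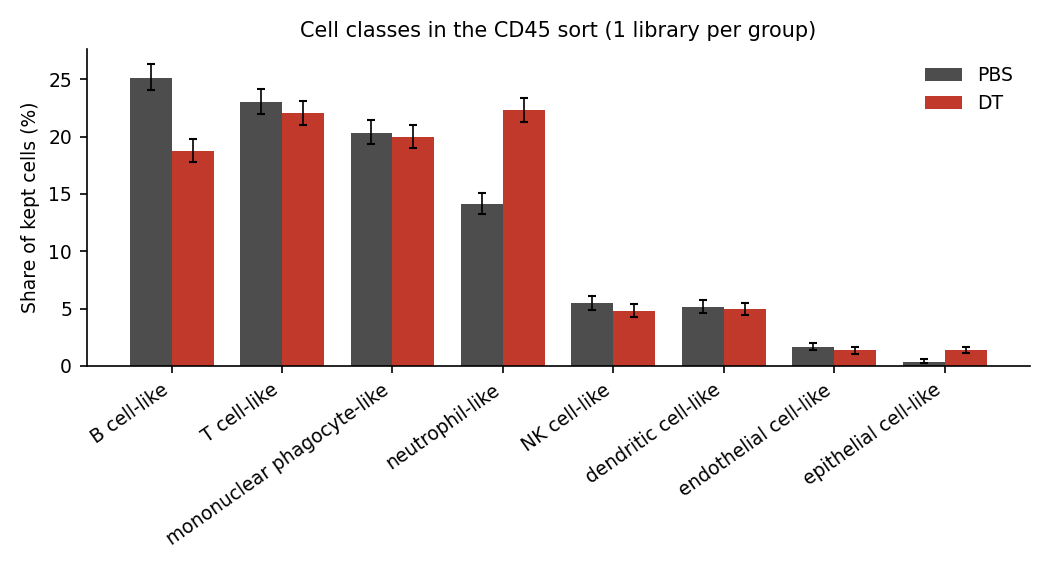
Percent of kept cells in 8 classes for the PBS (grey) and DT (red) libraries as bars, with lines for the Clopper-Pearson 95% interval, which covers counting error only. The neutrophil class lies at 14.2% in PBS and 22.3% in DT, and the B cell class at 25.1% and 18.7%.

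The libraries also differed in sex-linked RNA. Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254, GRCm38), had a log2 ratio of 2.82 in the T cell class, 2.76 in mononuclear phagocytes and 1.95 in B cells, while Ddx3y, a Y-linked helicase, had -1.98 in T cells and -1.48 in mononuclear phagocytes. Counting cells with UMIs of 4 Y-linked genes and none of Xist as male-called, and the reverse as female-called, 87.2% of called cells were male-called in PBS (85.9 to 88.4) and 31.9% in DT (30.2 to 33.7). The male-called share was 89.9% in PBS and 18.8% in DT for T cells, 82.8% and 43.5% for B cells, and 97.48% and 78.1% for neutrophils. Cells with neither signal were 2759 of 5651 in PBS and 2973 of 5896 in DT, and values within called cells leave them out. Neutrophil calls are weak: cells with both Xist and Y-linked UMIs were 1.36 times the number that chance would give in PBS and 1.00 times in DT. The labels give no sex of the animals, and values within called cells, an alternative chosen after seeing the data, are given below for leading lists and genes whose direction they turn or whose value they move by more than 1.5 times. Within male-called cells the neutrophil ratio was 2.57 and the B cell ratio was 1.18, on the other side of 1, while the T cell ratio was 0.580 in male-called and 1.53 in female-called cells. The regulatory T cell ratio was 0.477 in male-called cells (132 in PBS and 23 in DT) and 3.20 in female-called cells (8 and 136). The alveolar macrophage ratio was 0.672 in male-called cells (57 and 14 cells, interval 0.346 to 1.22). The nonclassical monocyte ratio was 0.783 in female-called cells (6 and 25 cells, interval 0.314 to 2.33). These alveolar macrophage and nonclassical monocyte intervals include 1.

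Mononuclear phagocytes of the DT library carried more RNA of genes tied to suppressive macrophages. Arg1 (chromosome 10, 24915221 to 24927484, GRCm38), the arginase that depletes arginine around suppressive macrophages, was 196 CPM in DT and 54.2 CPM in PBS, a log2 ratio of 1.76 (counting interval 1.71 to 2.00). Thbs1 (chromosome 2, 118111876 to 118127133, GRCm38), the matrix glycoprotein thrombospondin 1, was 422 CPM against 136 CPM, at 1.59 (1.54 to 1.72). Spp1, which encodes osteopontin, was 1.07 higher on the log2 scale, Ecm1, an extracellular matrix protein, 0.94 higher, and Vegfa, the growth factor for vessels, 0.91 higher. Per1 and Klf9, which glucocorticoids induce and the circadian clock drives, stood at 1.03 and 0.94, the early response gene Ier3 at 1.04, and the noncoding transcript Gm14023 at 0.93.

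Genes of patrolling monocytes and alveolar macrophages were among the lowest of the same class. Eno3, a muscle-type enolase, had a log2 ratio of -2.02, Treml4, a receptor of nonclassical monocytes, -1.84, Adgre4, an adhesion receptor, -1.52, Ace, the angiotensin-converting enzyme, -1.47, and Smpdl3b, a lipid phosphodiesterase, -1.37, and the ribonucleases Ear1 and Ear2 had -2.00 and -1.52. These genes lead the clusters whose shares were lower in DT: with clusters weighted the same in both libraries, Ace came to 0.04, Adgre4 to -0.27, Ear2 to -0.41, Treml4 to -0.61, Smpdl3b to -0.71, Eno3 to -0.80 and Ear1 to -0.92. Immunoglobulin RNA was lower as well, with Igkc, the kappa light chain, at -2.57 and Igha, the IgA heavy chain, at -4.19. Igha came to 0.29 once the cells with the highest doublet scores were left out and to 0.05 as a difference of mean deposited log2 values.

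Inflammatory cytokine and NF-kB genes were higher in DT mononuclear phagocytes in 18 of 24 measured members, with a median log2 ratio of 0.44, above all 10000 random lists matched on expression. Il6 stood at 1.84, the neutrophil-attracting chemokine Cxcl1 at 1.02, Cxcl2 at 0.60, Il1a at 0.96 and Il1b at 0.42, while Tnip1, an inhibitor of NF-kB, stood at -0.82. Lists of neutrophil genes were higher in the same class, mature neutrophil genes in 10 of 14 members (median 0.22) and Siglecf-high neutrophil genes in 11 of 13 (median 0.29). The mature list came to 0.08 without the highest doublet scores. Suppressive macrophage genes were higher in 14 of 19 members (median 0.22), among them Gpnmb at 0.89, Fn1 at 0.80 and Apoe at 0.65, whereas Retnla, a secreted marker of alternative activation, was -3.05 with UMIs in 0.609% of PBS and 0.340% of DT cells. Glycolysis and hypoxia genes were higher in 20 of 21 (median 0.24), with Mif at 0.64 and the enzyme Tpi1 at 0.43. Myeloid suppressor genes (11 of 17, median 0.24) included Cd14 at 0.81 and the prostaglandin synthase Ptgs2 at 0.49, but S100a8 at -0.21 and S100a9 at -0.30. Nos2, the inducible nitric oxide synthase, gave 0 UMIs over all PBS cells and 49 over all DT cells. It had fewer than 20 UMIs in each of the 6 classes, so this is no result about mononuclear phagocytes. Lipid and lysosome genes (16 of 22, median 0.18) included the protease Lgmn at 0.55, and Pparg, the regulator of alveolar macrophages, at -0.69. The chemokine list (17 of 26, median 0.21) held Ccl7 at 0.81 but Ccl22 at -1.02, and interferon-gamma targets (15 of 20) had a median of 0.13 with Cd274, which encodes PD-L1, at 0.30. Phospholipase and eicosanoid genes (9 of 19 higher, median -0.03) and MHC class II genes (7 of 15, median -0.01) lay within the range of random lists.

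In male-called cells alone, the medians of the NF-kB (-0.14), glycolysis (-0.12), myeloid suppressor (-0.25), chemokine (-0.04), interferon-gamma (-0.32) and mature neutrophil (-0.49, 0 of 14 higher) lists, with Cxcl2 (-0.25), Il1b (-0.26), Cd274 (-0.25), Ier3 (-0.01), Gm14023 (-0.80) and Vegfa (-0.36), lay on the other side of 0. The Siglecf-high list was 0.12, the suppressive list 0.53, Arg1 1.46, Thbs1 1.44 and Spp1 0.69, and as a difference of mean deposited log2 values Arg1 was 0.76, S100a8 0.02 and S100a9 0.17. With clusters weighted the same, the chemokine and interferon-gamma medians turned to -0.07 each and glycolysis came to 0.16 and Siglecf-high genes to 0.13, and without the highest doublet scores the myeloid suppressor median was -0.02.

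DT neutrophils held more of the activated, tumour-type state and less granule RNA. Cluster 4, led by Il1a, Ccl3 and Ccrl2, held 23.6% of PBS neutrophils (20.7 to 26.7) and 36.1% of DT neutrophils (33.5 to 38.7), and cluster 1, led by Retnlg, S100a9 and Mmp8, held 68.0% and 54.3%. Cxcl3, a neutrophil-attracting chemokine, was 1.05 higher on the log2 scale and the cytokine Mif 1.29. The transcriptional inhibitor Id2 stood at 1.25 and the UDP-glucose receptor P2ry14 at 1.16. The chemokine Ccl5, also a leading gene of a T cell cluster, was 1.63 higher, from 34 UMIs in PBS and 189 in DT. It was seen in only 3.25% of PBS and 3.96% of DT neutrophils, so few cells carry it. Klhl6, a ubiquitin ligase adaptor, stood at 1.28, the small GTPase Arf2 at 1.24, the long noncoding transcript Gm19951 at 1.19, the phosphatase Ptpn22 at 1.14 and the nuclear pore gene Nup153 at 1.06. Ngp, a granule protein of immature neutrophils, was -1.36, Lrg1 -0.92, the metalloreductase Steap4 -0.91, the glutathione synthesis gene Gclm -0.94, the DNA repair gene Xpc -0.89 and the acute phase gene Saa3 -1.19. Transcripts that neutrophils should lack were lower too: Scgb1a1 at -3.84, Igkc at -2.65, Ighm at -1.63 and H2-Aa at -0.95.

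Genes of Siglecf-high tumour neutrophils were higher in 10 of 13 members (median 0.40, above all random lists), with Siglecf itself at 0.74, Ccl3 at 0.69 and the tetraspanin Cd63 at 0.52, and Cd274 stood at 0.41. NF-kB genes were higher in 17 of 22 (median 0.31), with Tnfaip3 at 0.64, Tnf at 0.63 and Cxcl2 at 0.56, while Il1b stood at 0.01. Immature granule genes were higher in 3 of 12 (median -0.35, below all random lists), with Lcn2 at -0.53 and Ly6g at -0.48. The alarmins S100a8 and S100a9 stood at -0.34 and -0.38, and Arg2 at -0.24. Myeloid suppressor genes had a median of -0.14 (6 of 16 higher) and mature neutrophil genes -0.06 (5 of 14), the latter within its random range. Transcripts of the mitochondrial genome were lower in 12 of 13 members (median -0.53), while nuclear genes of oxidative phosphorylation were higher in 23 of 26 (median 0.30), with Uqcrb at 0.77 and Cox5a at 0.55.

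The 4691 genes with at least 100 UMIs in this class had a median of 0.09. Scaling by trimmed mean factors in place of CPM moved Il1b to -0.10, and means of deposited log2 values moved it to -0.14. Sex calls are weak in this class. In male-called cells the Siglecf-high (-0.05) and NF-kB (-0.10) medians, Cd274 (-0.22), Arg2 (0.14), Mif (-0.18) and Saa3 (1.04) lay on the other side of 0. In the same cells Ccl5 came to 0.09, Cxcl3 to 0.18, oxidative phosphorylation to 0.08, Id2 to 0.80 and Gm19951 to 0.79. With clusters weighted the same the Siglecf-high median was -0.01 and NF-kB 0.04.

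**Figure D3:**
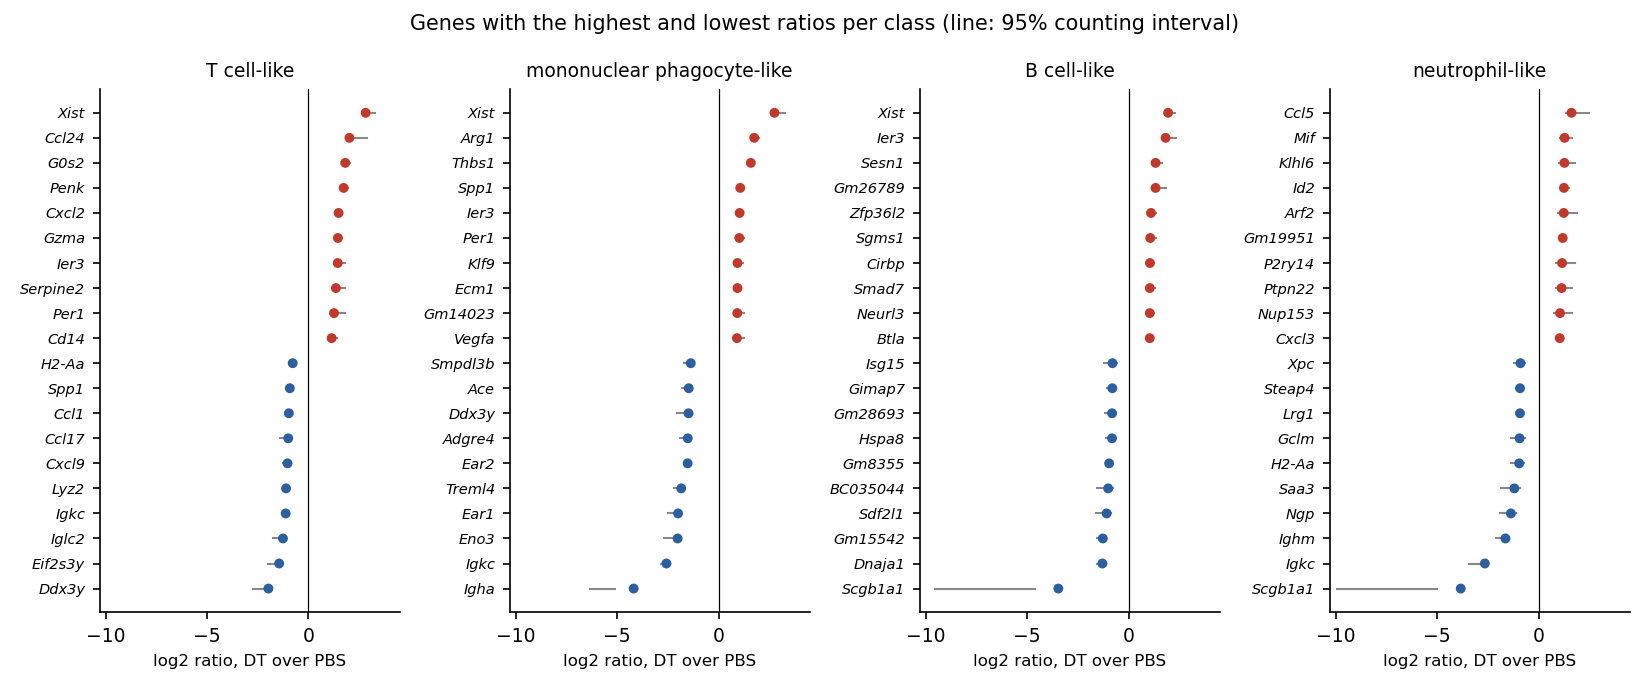
Log2 ratio DT over PBS of the 10 highest (red) and 10 lowest (blue) genes in each of 4 classes, as points with 5 CPM added, and lines for the 95% counting interval without that addition, so that points of genes with few UMIs lie nearer 0 than their lines. In mononuclear phagocytes Arg1 (1.76) and Thbs1 (1.59) follow Xist at the upper end, and Scgb1a1 is lowest in B cells (-3.46) and neutrophils (-3.84).

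B cells of the DT library held less RNA of interferon-stimulated genes and chaperones. Type I interferon targets were higher in 5 of 26 members and lower in 21 (median -0.34, below all random lists), with Ifit2 at -0.89, Ifit3 at -0.82 and Isg15, the ubiquitin-like modifier, at -0.79. The chaperones Dnaja1 and Hspa8 stood at -1.29 and -0.81, and Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, at -1.08. Higher in DT were Ier3 at 1.83, Sesn1, a stress sestrin that p53 induces, at 1.33, the RNA decay factor Zfp36l2 at 1.11, Sgms1, which makes sphingomyelin, at 1.07, Cirbp, a cold-induced RNA-binding protein, at 1.06, Smad7, the inhibitor of TGF-beta signalling, at 1.05, the ubiquitin ligase Neurl3 at 1.05 and Btla, an inhibitory receptor, at 1.05. The antisense transcript Gm26789 was 1.33, and the other genes at the lower end were Scgb1a1 (-3.46), the pseudogenes Gm15542 (-1.27) and Gm8355 (-0.96), BC035044 (-1.004), Gm28693 (-0.81) and the GTPase Gimap7 (-0.80).

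Most of this class lay in different clusters in the 2 libraries. Cluster 0, led by Ighd, Cd55 and Fcer2a, held 37.3% of PBS B cells and 71.6% of DT B cells, and cluster 2, led by Tnfrsf13c, Ms4a1 and Ly6d, held 60.0% and 24.5%. The dissociation and heat shock list had a median of -0.22 (9 of 21 higher), and activation and isotype genes -0.11 (9 of 19), with Cd86 at -0.56, Cd83 at -0.53 and Ighd, the IgD chain, at 0.51. Inflammatory NF-kB genes were higher in 19 of 20 (median 0.43), with Cxcl2 at 0.90 and Nfkbiz at 0.86, as were mature neutrophil genes (11 of 14, median 0.25) and myeloid suppressor genes (12 of 16, median 0.20). Ribosomal protein genes were higher in 24 of 86 (median -0.08). Red cell RNA was higher in 4 of 4 members (median 4.17), with Hba-a1 at 20 UMIs in PBS and 683 in DT, and turned to -0.69 without the highest doublet scores, which also took the NF-kB median to 0.10, mature neutrophil to 0.21 and myeloid suppressor to 0.07.

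The interferon median was -0.25 in male-called and -0.18 in female-called cells, and -0.15 with clusters weighted the same, which also brought mature neutrophil genes to 0.07, myeloid suppressor genes to 0.03, Sgms1 to 0.58, Neurl3 to 0.57 and Smad7 to 0.47. The activation and isotype median turned to 0.27 in female-called cells, where mature neutrophil genes stood at 1.35 and myeloid suppressor genes at 0.94, and to 0.08 with a filter of at least 500 genes and 1000 UMIs.

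T cells of the DT library had higher RNA of regulatory and activation genes, while most cytotoxic genes were slightly lower. The regulatory T cell programme was higher in 11 of 12 members (median 0.36, above all random lists), with Areg, the repair factor amphiregulin, at 1.21, the interleukin-33 receptor Il1rl1 at 0.77, the costimulatory receptor Tnfrsf4 at 0.67 and the checkpoint receptor Ctla4 at 0.66. Activation genes were higher in 12 of 15 (median 0.19) and checkpoint genes in 8 of 12 (median 0.21), with Pdcd1, which encodes PD-1, at 0.24 but Cxcr6, a tissue-homing receptor, at -0.70. Cytotoxic genes had a median of -0.10 (6 of 16 higher), with Gzmb at 0.20, Ifng at -0.20, Ccl4 at -0.58 and Gzmk at -0.64. Gzma, a granzyme that also leads the NK cell cluster, stood at 1.45, from 558 UMIs in PBS and 1483 in DT. It was seen in only 4.69% of PBS and 5.77% of DT T cells, so few cells carry it. Penk, which encodes the opioid precursor proenkephalin, was 276 CPM in DT and 79.5 CPM in PBS (log2 ratio 1.73, counting interval 1.65 to 1.94), Serpine2, a protease inhibitor, was 1.35 higher, and Per1 was 1.26 higher.

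Targets of p53 were higher in 21 of 23 members (median 0.22), with Bbc3, a trigger of apoptosis, at 0.56 and Phlda3 at 0.46, and S phase genes in 18 of 20 (median 0.25), with Mcm2 at 0.38. Genes of G2 and M phase (13 of 18, median 0.15), naive and memory genes (7 of 10, median 0.07) and cell death genes (13 of 17, median 0.07, with Bcl2 at 0.57) lay within the ranges of random lists. In male-called cells the medians of the regulatory (-0.10), activation (-0.18), checkpoint (-0.47) and p53 (-0.02) lists, Pdcd1 (-0.72) and Gzmb (-0.30) lay on the other side of 0, S phase was 0.00, Gzma 0.14 and Ifng -2.53, while Penk was 1.23 and Per1 1.72.

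RNA of other cell types moved with the group in this class. Mature neutrophil genes were higher in 13 of 14 members (median 0.63), with G0s2 at 1.81, and NF-kB genes in 15 of 21 (median 0.50), with Cxcl2 at 1.49, Il1b at 0.95 and Ier3 at 1.44, and the myeloid genes Ccl24 and Cd14 stood at 2.02 and 1.14. Without the highest doublet scores these came to 0.04 and 0.08 for the lists, 0.22 for G0s2, 0.32 for Cxcl2, 0.16 for Il1b, 0.94 for Ier3, 0.32 for Ccl24 and 0.62 for Cd14. MHC class II genes were higher in 2 of 15 (median -0.44), with H2-Aa at -0.78, and the antigen-presenting and B cell transcripts Lyz2 (-1.11), Cxcl9 (-1.03), Ccl17 (-0.998), Spp1 (-0.92), Igkc (-1.13) and Iglc2 (-1.26) were lower, as were the chemokine Ccl1 (-0.97) and Y-linked Eif2s3y (-1.45). Red cell RNA was higher in 4 of 4 members (median 4.12), with Hba-a1 at 10 UMIs in PBS and 553 in DT, seen in 0.462% of DT T cells. No member had 20 UMIs without the highest doublet scores. Lyz2 turned to 0.07 without the highest doublet scores, and Cxcl9 turned to 0.28 and Ccl17 to 0.27 with coarser clusters (Leiden resolution 0.5). As differences of mean deposited log2 values Ccl1 (0.07), Spp1 (0.01) and Cxcl9 (0.01) lay on the other side of 0.

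**Figure D4:**
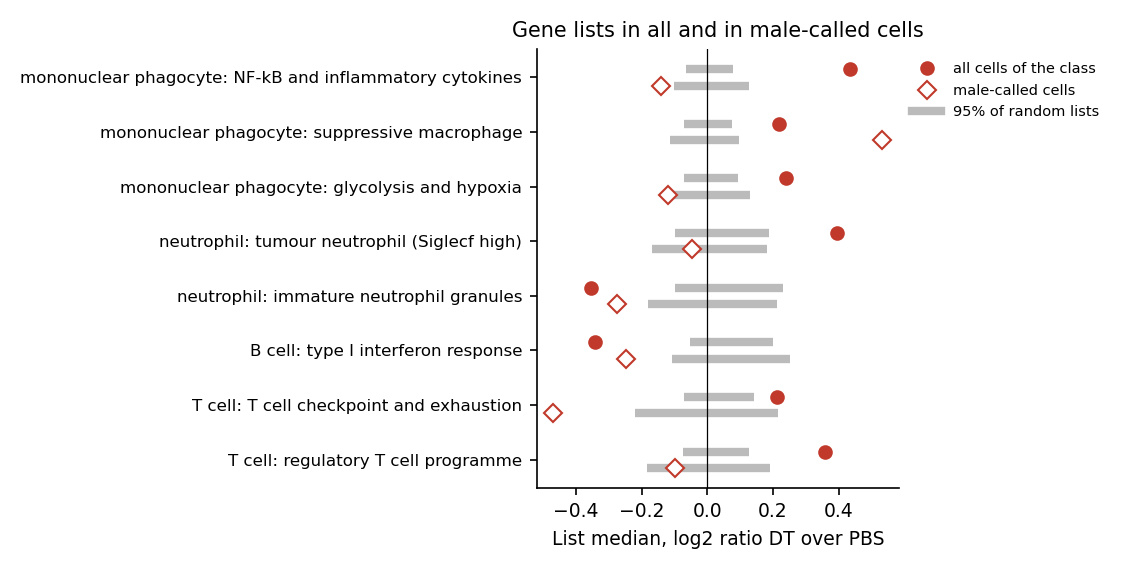
Median log2 ratio DT over PBS of 8 gene lists in their classes, for all cells of the class (filled circles) and for male-called cells alone (open diamonds), with grey bars for the central 95% range of random lists matched on expression. The mononuclear NF-kB median lies above its bar in all cells (0.44) and at -0.14 in male-called cells, while the suppressive macrophage median lies above its bar in both (0.22 and 0.53).

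NK cells of the DT library had less RNA of chemokines and of several effector genes. Ccl4 and Ccl3, chemokines that activated NK cells release, had log2 ratios of -1.71 and -1.46, Tgtp2, an interferon-induced GTPase, -1.33, and Ifng -0.90, while Gzmb stood at 0.24. Cytotoxic effector genes were higher in 4 of 16 members (median -0.20), with Tbx21, the master regulator of interferon-gamma in these cells, at -0.56. Type I interferon targets (5 of 21 higher, median -0.29) included Isg15 at -1.14, the chemokine list (4 of 15) had a median of -0.23, and MHC class I genes (4 of 17) had -0.15, each below the range of random lists. S100a9, abundant in neutrophils, was 22.8 CPM in PBS and 208 CPM in DT (log2 ratio 2.94) and Cxcl2 stood at 2.66, which came to 0 with free RNA at 10% of UMIs subtracted. Mature neutrophil genes as a list (4 of 6 higher, median 0.10) lay within the range of random lists. With members of at least 100 UMIs the chemokine median was -0.01.

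Dendritic cells of the DT library had less RNA of lipid and lysosome genes, a list higher in 4 of 19 members (median -0.15), with Ctsb at -0.56 and Ctsl at -0.54, but Apoe, the lipid carrier, at 1.09. Ly6d, a marker of plasmacytoid cells that also leads a B cell cluster, and the transcript Gm34680, a leading gene of the plasmacytoid cluster, stood at -1.71 and -1.27, and at -1.11 and -0.74 with clusters weighted the same. Heat shock and dissociation genes had a median of -0.21 (7 of 21 higher), with the chaperone Dnajb1 at -0.97, and MHC class II genes had 0.07 (8 of 15), within the random range. Gzma stood at 1.14, S100a8 at -0.88 and S100a9 at -0.75. Apoe came to 0.56 with coarser clusters and Gzma to 0.67 without the highest doublet scores. As differences of mean deposited log2 values Apoe (-0.04) and S100a9 (0.31) lay on the other side of 0, and Gzma was 0.09 and S100a8 -0.31.

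The share of cycling cells among all cells did not differ detectably at this depth. With each cell thinned to 1000 UMIs, 78 of 5449 PBS cells (1.43%, 1.13 to 1.78) and 78 of 5587 DT cells (1.40%, 1.11 to 1.74) had UMIs of at least 2 of 6 genes of mitosis, among them Mki67, Top2a and Cdk1. Without thinning, 184 of 5651 cells (3.26%) and 226 of 5896 cells (3.83%) did. Clusters led by Mki67 and Top2a form the proliferating class, so the T cell class holds only the cycling cells left outside them, 3 of 1284 and 2 of 1279 cells with thinning and 29 of 1302 and 48 of 1299 without (ratio 1.66, 1.03 to 2.73), which says little about T cell cycling.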

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

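All tests in this part were chosen only after the result was seen. Cells named epithelial made up 1.36% of DT cells although the sort was for CD45, which is meant to leave such cells out. These 80 cells were shallow, with a median of 992.5 UMIs against 8627 in the 21 PBS cells. The share ratio of 3.65 came to 2.34 with at least 500 genes and 1000 UMIs, and to 0.990 with each cell named alone. Female-called cells, with Xist and no Y-linked UMIs, made up 68.1% of sex-called DT cells, a signal in genes that no comparison of the design uses. Within called cells the share ratios lay on opposite sides of 1, with intervals that leave out 1, at 0.580 in male-called and 1.53 in female-called T cells, 0.760 and 1.33 for mononuclear phagocytes, 1.18 and 0.506 for B cells, and 0.477 and 3.20 for regulatory T cells. Dendritic cells (0.942 and 1.39) and epithelial cells (1.37 and 0.161) also lay on opposite sides of 1, but 1 lay inside both dendritic intervals and the male-called epithelial one, and the epithelial ratios rest on 4 and 2 male-called and 7 and 6 female-called cells. Those differences between male-called and female-called cells were not tested. Cells with neither signal, which these ratios leave out, were 2759 of 5651 in PBS and 2973 of 5896 in DT. In DT they were 527 of 1299 T cells but 1022 of 1314 neutrophils. A share within called cells therefore also depends on how often each class is called, which the counting intervals do not cover.

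Sex-linked RNA differed between the libraries, and pools that hold male and female cells in different proportions may account for it: cells with both Xist and Y-linked UMIs occurred at 0.308 times the number that chance would give in the library with the higher such ratio, so both signals sat mostly in separate cells. In neutrophils the same ratio was 1.36 in PBS and 1.00 in DT, so calls there are weak. Whether this mix is the whole cause of the higher neutrophil share remains open: the ratio was 2.57 in male-called cells, and the 1.91 in female-called cells rests on 6 PBS neutrophils. Whether animals or sexes differ in the mononuclear NF-kB list stays open: its median was -0.14 in male-called cells against 0.44 in all cells, but mature neutrophil genes turned in the same cells, from 0.22 to -0.49. An effect of the toxin that differs by sex or animal stays open as the biological alternative and was not tested.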

How the results depend on the processing

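Alternatives that left out doublet scores, used sex-called cells, gave clusters the same weight or took means of deposited log2 values were chosen after seeing the data, and the others were fixed in advance. No paired analysis was possible because each group is 1 library, which also rules out leaving out a replicate. A mitochondrial limit of 20% and keeping doublets changed nothing, since no cell exceeded 8.0% and none had been removed. Among the settings fixed in advance, 67 of 71 share ratios, 377 of 416 list medians and 1269 of 1551 gene ratios stayed close to the main value, with 1, 4 and 3 reversed. Among those added, 13 of 30, 79 of 151 and 277 of 560 did, with 2, 18 and 19 reversed. A share was close when it lay inside the main counting interval. For genes and lists, the shift from the main value could not exceed the reach of the counting interval, or of the random range, to either side of its middle. Only shares whose interval left out 1, lists outside their random range and genes past the size rule were counted as reversed when they turned, so other values below also lie on the other side of 1 or 0. Depth limits what the UMI filter and small classes can show, and intervals cover counting error only. For the values that follow, the cause was not tested.

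Share ratios in male-called cells were 0.580 for T cells, 0.760 for mononuclear phagocytes, 1.18 for B cells, 2.57 for neutrophils, 1.07 for NK cells, 1.37 for epithelial cells, 0.672 for alveolar macrophages and 0.477 for regulatory T cells. In female-called cells they were 1.53 for T cells, 1.33 for mononuclear phagocytes, 0.506 for B cells, 1.91 for neutrophils, 1.39 for dendritic cells, 1.12 for NK cells, 0.161 for epithelial cells, 0.783 for nonclassical monocytes and 3.20 for regulatory T cells. Of these, the neutrophil, epithelial, nonclassical monocyte and regulatory T cell ratios rest on 6, 7, 6 and 8 PBS cells. The neutrophil ratio was 1.37 at Leiden resolution 2, and the epithelial ratio was 0.990 with each cell named alone. The nonclassical monocyte ratio was 0.236 with at least 500 genes and 1000 UMIs and 0.287 with at most 5% mitochondrial UMIs.

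List medians in male-called mononuclear phagocytes were -0.14 (NF-kB), 0.53 (suppressive), -0.12 (glycolysis), -0.25 (myeloid suppressor), -0.0425 (chemokines), -0.32 (interferon-gamma) and -0.49 (mature neutrophil). In male-called cells of the neutrophil class they were -0.0472 (Siglecf-high) and -0.10 (NF-kB), and in male-called T cells -0.47 (checkpoint), -0.18 (activation), -0.10 (regulatory) and -0.0242 (p53). Female-called B cells gave -0.18 for type I interferon and 0.27 for activation and isotype. With clusters weighted the same, mononuclear medians were 0.31 (NF-kB), 0.16 (glycolysis), -0.0653 (chemokines) and -0.0691 (interferon-gamma), the Siglecf-high median was -0.0113 and the B cell interferon median -0.15. Without the highest doublet scores, the mononuclear NF-kB median was 0.32, myeloid suppressor -0.0175 and B cell red cell RNA -0.69. With each cell weighted the same, mononuclear NF-kB was 0.31 and B cell activation 0.0019, which was also 0.0815 with at least 500 genes and 1000 UMIs, 0.0007 with at most 5% mitochondrial UMIs and 0.076 at Leiden resolution 0.5. With free RNA subtracted, the B cell interferon median was -0.48.

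Among genes past the size rule for named genes (a ratio of at least 1.5, 100 UMIs and 50 CPM), those that reversed in male-called cells were Ccl24 (-0.0614) in T cells, Cxcl2 (-0.25), Ier3 (-0.0123), Gm14023 (-0.80) and Vegfa (-0.36) in mononuclear phagocytes, and Mif (-0.18) and Saa3 (1.04) in neutrophils. Eif2s3y in T cells (0.68) and Ddx3y in mononuclear phagocytes (0.0879) turned as well, but male calls rest on these genes, so the selection sets those values. Named genes short of that rule also lay on the other side of 0 in male-called cells: Pdcd1 (-0.72), Arg1 (-1.57) and Gzmb (-0.30) in T cells, Cd274 (-0.25), Arg2 (-0.49), Ifng (-1.29), Gzmb (-0.70) and Il1b (-0.26) in mononuclear phagocytes, Cd274 (-0.22), Arg2 (0.14) and Gzmb (-0.32) in neutrophils, and S100a8 (0.22) and S100a9 (0.31) in B cells. Without the highest doublet scores, Lyz2 in T cells was 0.068 and Igha in mononuclear phagocytes 0.29. At Leiden resolution 0.5, T cell Cxcl9 was 0.28 and Ccl17 0.27, and at resolution 2 Ccl17 was 0.24. Ace in mononuclear phagocytes was 0.0406 with clusters weighted the same. Means of the deposited log2 values gave 0.0099 for Cxcl9, 0.0686 for Ccl1 and 0.0119 for Spp1 in T cells, 0.0461 for Igha in mononuclear phagocytes, 0.31 for S100a9 and -0.0441 for Apoe in dendritic cells, and -0.0012 for Il1b in NK cells.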

Other observations

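All tests in this part were chosen only after the result was seen. Genes that glucocorticoids induce were higher in DT in each of the 6 classes compared, with list medians of 0.51 in T cells, 0.51 in mononuclear phagocytes, 0.64 in B cells, 0.28 in neutrophils, 0.28 in dendritic cells and 0.52 in NK cells. Per1, Klf9, Fkbp5, which encodes a chaperone of the steroid receptor, and Tsc22d3, the anti-inflammatory factor GILZ, were each higher in 6 of 6 classes. Per1 ranged from 0.57 to 1.26 and Klf9 from 0.28 to 1.42 on the log2 scale. Of the same list, Zbtb16 was higher in 0 of 3 classes and Sgk1 in 3 of 6. Heat shock proteins were lower, with medians of -0.27 in T cells, -0.19 in mononuclear phagocytes, -0.44 in B cells, -0.13 in neutrophils, -0.07 in dendritic cells and -0.29 in NK cells, of which the dendritic cell value lay within its range for random lists. The chaperones Hspa8, Dnaja1, Dnajb1 and Hsp90ab1 were higher in 0 of 6 classes. Cirbp and Rbm3, RNA-binding proteins that cold induces, were higher in 6 of 6. Per1, Klf9, Hspa8, Dnaja1 and Cirbp are also among the genes ranked highest or lowest in a class of these same data. They therefore lend these lists no independent support.

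As a source of the glucocorticoid pattern, the sex mix of the pools is argued against. The glucocorticoid median lay above the random range in male-called cells of 4 of 4 classes with enough such cells. These include the neutrophil class, where sex calls are weak, so the argument rests on T cells, mononuclear phagocytes and B cells. For the lower heat shock RNA the sex mix was not tested. A longer or warmer dissociation of the PBS lungs stays open, as the lower heat shock and higher Cirbp and Rbm3 RNA go with a temperature difference. Immediate early genes, which dissociation induces, lay below their range in 1 of 6 classes, dendritic cells (-0.17), but also in male-called mononuclear phagocytes (-0.14). With all cells of the class they lay above it in T cells (0.28) and mononuclear phagocytes (0.27, 12 of 12 higher), as in male-called T cells (0.45). That direction goes against a longer dissociation of the PBS lungs. Without the highest doublet scores they lay above it in mononuclear phagocytes (0.25) but not in T cells (0.09) or B cells (-0.03). A different time of day at harvest could not be excluded: clock output genes lay outside their range in 0 of 3 classes, but 7 or fewer were measured in a class, and in mononuclear phagocytes they lay above it in male-called cells (0.70) and without the highest doublet scores (0.21). A stress hormone response in the toxin-treated mice may be a biological explanation, and it was not tested.

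Myeloid RNA in the T cell class of DT may come from droplets with more than 1 cell. Neutrophil-specific list members were parted in 2, and cells with at least 2 UMIs of one part were left out. These were 20.3% or 9.08% of the DT class and 15.4% or 6.22% of the PBS class. The median of the other part then came to -0.04 or 0.238 times its value. Such a cut also takes out single T cells that carry free RNA, so it cannot tell these from droplets with more than 1 cell. Free RNA shared by all droplets stays open: the NK cell median of that list lay at -0.53 relative to the T cell median, but it rests on 6 members against 14. The myeloid suppressor list was higher in NK cells (0.77) than in T cells (0.47), and came to 0.06 in NK cells with free RNA subtracted. Contact between T cells and neutrophils in the DT lungs, which would also give such droplets, stays open and was not tested.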
